A study of Mus musculus with 9 samples.

How the data were processed

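RNA was measured in hair follicle stem cells of male C57BL/6J mice at 3 ages, 3, 19 and 24 months, with 3 libraries per age and 9 in all. The cells were sorted from back and belly skin as keratinocytes with high CD49f (integrin alpha 6, a receptor for basement membrane laminins) and surface CD34, which together mark the bulge of the follicle. The replicate numbers in the labels are 1, 2 and 3 at 3 and 19 months and 2, 3 and 4 at 24 months. No label says that the libraries of an age came from separate animals, so p-values measure only the spread between these libraries, which may be technical. The running numbers in the labels go from 6058 to 6060 for the 3-month libraries and from 6067 to 6072 for the 19- and 24-month libraries, and 2 barcodes of the 3-month libraries return at 19 months, so those libraries cannot have shared a pool. A pool or batch difference between 3 months and the older ages therefore cannot be told apart from age, while the 19- and 24-month libraries carry consecutive numbers.

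The deposited table holds 1 FPKM value (fragments mapped to a transcript, scaled by its length and by the mapped fragments of the library) for each of 37980 rows and 9 libraries. TopHat, Cuffdiff and the genome build NCBIM37 are named in the submitters' processing notes, and their versions and settings are not given in the sources used here. The depth of each library is unknown, since the low values gave no usable step for 1 read. The FPKM of each library summed to between 8705000 and 68770000 over all rows, because a few very short RNA rows take enormous values, and to between 544300 and 736400 over protein-coding rows. Median FPKM over the tested protein-coding genes lay between 10.0 and 11.3. No per-read interval or detection limit could be given.

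Some zeros in the table are failed estimates. Krt15, a keratin of the follicle bulge, was listed at 0 in all 9 libraries. In 36 rows, every library of an age was listed at exactly 0 while every library of another age reached at least 5 FPKM. These included Krt5 and mt-Co1, both protein-coding. Such rows are reported as listed at 0, with values per library and no change claimed. Gapdh, at 4.05 to 7.24 FPKM, shares near-identical sequence with many pseudogenes, and its value is uncertain, as is that of other genes with near-identical copies, such as ribosomal protein genes and the alpha globins. Strand use in the quantification is not given in the sources used here, so genes that overlap others are uncertain too.

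The test fixed before the data were examined was limma (version 3.58.1, R version 4.3.3) with a mean-dependent prior variance on log2(FPKM + 1), with all 9 libraries in 1 model, on rows with at least 1 FPKM in at least 3 libraries. It was run on 14275 rows, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Errors given with FPKM are SDs over 3 libraries, and those given with log2 fold changes are limma's standard errors unless said otherwise. An F test asked for a change at any age.

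A second fit, on protein-coding genes alone, was chosen after the data had been seen and after several fits had been tried, when it was already known to call more genes. The fits tried were the fixed one, the fixed one without the rows listed at 0, the protein-coding one, and robust, quantile-normalised and pseudocount 0.1 versions of the fixed and protein-coding fits. The reason for leaving out other gene types was their spread: the median SD within an age was 2.13 on the log2 scale in 703 small RNA rows and 0.21 in 11511 protein-coding rows, and all rows share the prior variance and the adjustment. Gene types came from the GENCODE M21 annotation by Ensembl identifier, which matched 32916 of the 37980 rows. That annotation is on another genome build than the table, so no coordinates are printed. The protein-coding fit held 11509 genes, with the rows listed at 0 left out. For single genes, fixed-fit values are named as such, and others that follow the words protein-coding fit come from the second fit.

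The fixed fit called 40, 29 and 7 genes at 19 against 3, 24 against 3 and 24 against 19 months, and 32 in the F test. With the rows listed at 0 left out and nothing else changed, it called 27, 0, 0 and 0. The protein-coding fit called 180, 442, 107 and 523. Of named genes called in the fixed fit and not listed at 0, 0 of 15, 0 of 13 and 0 of 1 kept the call in all 9 fits that left out 1 library; in the protein-coding fit 17 of 45, 24 of 68 and 11 of 35 kept it. A robust prior on the fixed set, an alternative planned before the data were examined, called 72, 224, 27 and 152.

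Gene lists were fixed before the data were examined, 33 in number, 9 of them markers of other cell types that the sort could hold. Lists with at least 3 tested members, 30 in all, were tested with camera at a preset correlation of 0.01 in the fixed fit, with adjustment over 90 tests. Of these, 24 passed with the preset correlation and 0 with a correlation estimated from the residuals. In the protein-coding fit 31 of 90 passed, and again 0 with an estimated correlation. Camera values come from the fixed fit unless the protein-coding fit is named beside them. The directional test of fry asked whether the genes of a list moved, on balance, one way. It passed 3 of 90 tests in each fit, and its values, like the counts and medians of list members, come from the protein-coding fit. The endothelial, skeletal muscle and adipocyte marker lists had 2, 1 and 1 tested members and were not tested as lists.

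Named genes were chosen by a rule fixed before the data were examined: for each comparison the 8 largest rises and falls among called genes whose libraries did not overlap between the ages, filled to 4 by unadjusted p, plus up to 3 called members of each list or its 2 highest members, plus a fixed set of follicle stem cell, cell cycle and sex-linked genes. The rule was applied to both fits, and genes named outside it are said to be so. Some genes that the rule picked are counted but not reported here. Alternatives were another pseudocount, no filter on low values, quantile normalisation, median-of-ratios scaling, the replicate number as a block, only the libraries of the ages compared, a minimum change, a robust prior and each library left out in turn.

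The fitting code was tested on simulated data with the means and spreads of the real genes, with 200 genes changed at 24 months. The noise was normal and drawn independently for each gene. The rates below therefore check the code and do not cover genes that move together within libraries. For 24 against 3 months, the fixed fit over 14275 rows recovered 59% of changes of 1 and 96% of changes of 2 on the log2 scale, with 6 false calls. For the same comparison the protein-coding fit over 11509 genes recovered 82% and 99%, with 9 false calls. Plots were drawn with matplotlib (version 3.10.9, Python version 3.11.15).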

Results

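The transcriptome of sorted basal hair follicle stem cells was compared between male mice of 3, 19 and 24 months, to ask how expression in these cells differs with age. Each age had 3 libraries, and their depth was unknown. In the fit of protein-coding genes, log2 values of libraries of the same age correlated across genes at 0.977 to 0.986 (9 pairs) and those of different ages at 0.965 to 0.985 (27 pairs). Genes are not independent replicates. The first principal component held 26.3% of the variance. It placed the 3-month libraries between -24.68 and -16.13 and the older libraries between 2.49 and 19.49.

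Transcripts that define the sorted population were abundant at every age. Cd34 stood at 548 ± 84.9, 626 ± 6.00 and 472 ± 60.9 FPKM at 3, 19 and 24 months (SD, n = 3 each). Itga6, which encodes CD49f, stood at 90.8 ± 22.6, 84.5 ± 14.7 and 87.4 ± 8.88 FPKM, and Krt14, a basal keratin, at 3805 ± 941, 4417 ± 495 and 5304 ± 1185 FPKM. None of these 3 genes passed the fixed fit at any comparison (smallest limma adjusted p = 0.344). The Y-linked Ddx3y lay between 10.7 and 20.5 FPKM in the 9 libraries, and Xist, the X-inactivation transcript, between 0.172 and 0.570 FPKM. Krt5, the partner of Krt14, was listed at 0 in all 3 libraries of 19 months and at 2160.4 to 7576 FPKM in the other libraries. The mitochondrial mt-Co1 was listed at 0 in every library of 19 and 24 months and at 5739 to 6507 FPKM at 3 months, and mt-Rnr2 was listed at 0 in every 24-month library. Krt15 was listed at 0 in all 9 libraries. The replication-linked Mki67 was low, at 2.51 ± 0.415, 2.91 ± 1.27 and 2.04 ± 0.194 FPKM, and the senescence-linked Cdkn2a was listed at 0 in 7 of 9 libraries and at up to 0.108 FPKM in the others. With some zeros of the table false and the depth unknown, no low level of Cdkn2a is claimed. Of 41 tested cell cycle genes, 0 passed limma's test at any comparison in the protein-coding fit. Over all 11509 genes of that fit, 180, 442 and 107 passed at 19 against 3, 24 against 3 and 24 against 19 months. With so small a share of all genes called, 0 of 41 does not set the cell cycle genes apart.

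At 19 against 3 months, Tsc22d3, a leucine zipper protein induced by glucocorticoids, fell from 913 ± 251 to 126 ± 28.0 FPKM (SD, n = 3 each). Its log2 change was -2.84 ± 0.28 (SE, limma adjusted p = 0.013 in the fixed fit). Glul, glutamine synthetase, fell by 1.95 ± 0.25 (adjusted p = 0.0337). Far2, which makes fatty alcohols for wax synthesis, fell from 7.68 ± 1.15 to 1.25 ± 1.06 FPKM (adjusted p = 0.0477). Gng11, a G protein gamma subunit, rose from 0.384 ± 0.0984 to 3.86 ± 1.34 FPKM (log2 1.78 ± 0.19, adjusted p = 0.0197), and Vit, the matrix protein vitrin, from 3.38 ± 0.717 to 12.1 ± 2.79 FPKM (log2 1.58 ± 0.18, adjusted p = 0.0197). Usp18, which removes the ubiquitin-like ISG15, rose by a log2 of 1.15 ± 0.16 (adjusted p = 0.037), and H2-M3, a nonclassical MHC class I gene, by 1.13 ± 0.15 (adjusted p = 0.0362).

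The fixed fit called 40 of 14275 table rows at 19 against 3 months, 8 higher and 32 lower, of which 7 were listed at 0 at an age. At an unadjusted p under 0.05 it held 1993, against 714 by chance. The protein-coding fit, chosen after the data had been seen, called 180 of 11509 genes, 69 higher and 111 lower, including 30 of the 40. Of 15 named genes called in the fixed fit and not listed at 0, 0 kept the call in all 9 fits that left out 1 library. The call of Tsc22d3 was lost without 3 months replicate 2 (adjusted p = 0.0696), as were those of Gng11 and Vit (0.0966 for both), and that of H2-M3 (0.121). The calls of Far2, Glul and Usp18 were lost without 19 months replicate 2 (0.218, 0.136 and 0.132). The fixed fit called 9, 12 and 21 without 3 months replicates 1, 2 and 3, 21, 11 and 18 without 19 months replicates 1, 2 and 3, and 21 and 26 without 24 months replicates 3 and 4. The protein-coding fit called 69 and 92 without 3 months replicates 1 and 2, and 85 and 72 without 19 months replicates 2 and 3.

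In the protein-coding fit the secreted factor Angptl7, a transcript of the bulge, fell from 1159.7 ± 452 to 267 ± 98.2 FPKM at 19 months (log2 -2.10 ± 0.32, limma adjusted p = 0.00363). Cish, a feedback inhibitor of cytokine signalling, fell by 1.49 ± 0.21 (adjusted p = 0.00214), and Pfkfb3, a regulator of glycolysis, fell by 1.66 ± 0.24 (adjusted p = 0.00214). Upp1, uridine phosphorylase, rose from 11.2 to 33.4 FPKM (log2 1.46 ± 0.21, adjusted p = 0.00214). The calls of these 4 genes, and of Tsc22d3, Far2, Gng11, Vit and Usp18, were kept in this fit whichever of the 9 libraries was left out. Fkbp5, a glucocorticoid-induced immunophilin, fell by 2.22 ± 0.40 (adjusted p = 0.0118, and 0.0747 without 3 months replicate 1). The transcription factor gene Mef2c rose by a log2 of 1.44 ± 0.30 (adjusted p = 0.0242, and 0.106 without 3 months replicate 1).

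Of 32 tested genes of hair follicle stem cell identity, 3 were called higher and 1 lower at 19 months in the protein-coding fit. The chemokine gene Cxcl14 rose from 123 to 261 FPKM (log2 1.07 ± 0.19, adjusted p = 0.00903). The transcription factor genes Sox9 and Nfatc1 rose by log2 changes of 0.66 ± 0.15 (adjusted p = 0.0348) and 0.78 ± 0.17 (adjusted p = 0.0264), and the fourth gene was Angptl7. Sox9 and Nfatc1 did not pass the fixed fit (adjusted p = 0.162 for both). Their calls in the protein-coding fit were lost without 3 months replicate 1 or 2 or 19 months replicate 2 or 3 (highest adjusted p = 0.15 and 0.128). Adjusted over the list alone, 7 members were higher and 2 lower. Camera gave adjusted p = 0.214 in the fixed fit and 0.0422 in the protein-coding fit (adjusted p = 0.639 with an estimated correlation, fry adjusted p = 0.234). In the fixed fit the list also held Krt5, listed at 0 in every 19-month library, which entered that camera test as a large fall. The camera values of the fits therefore rest on different members, and the fixed-fit value is distorted by that row. Without 3 months replicate 1 or 19 months replicate 1 or 3 the list passed in neither fit (highest camera adjusted p = 0.229 in the protein-coding fit, without 3 months replicate 1).

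WNT and Notch signalling each had 2 genes called lower at 19 months and 0 called higher. Lef1 and Ccnd1, of 24 tested WNT genes, fell by 1.14 ± 0.24 and by 0.66 ± 0.15 (fixed-fit camera adjusted p = 0.271). Jag1 and Notch2, a ligand and a receptor among 11 Notch genes, fell by 0.78 ± 0.14 and by 0.73 ± 0.17. For the Notch list camera in the fixed fit gave adjusted p = 0.0304 (adjusted p = 0.508 with an estimated correlation, fry adjusted p = 0.0687), and 0.0663 and 0.0669 without 3 months replicate 3 or 19 months replicate 1. The 4 single-gene calls were each lost in at least 4 leave-one-out fits (highest adjusted p = 0.111, 0.159, 0.0647 and 0.197). Adjusted over the list alone, 4 WNT genes were lower and 3 higher, and 2 Notch genes were lower.

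The sebaceous gland list holds genes of lipid synthesis and storage. At 19 against 3 months, of 13 tested members 6 were called lower and 0 higher in the protein-coding fit. Cidea, a lipid droplet protein, fell from 7.07 ± 1.34 to 1.07 ± 1.10 FPKM (log2 -2.08 ± 0.32), and Scd1, the stearoyl-CoA desaturase, from 41.9 to 18.9 FPKM (log2 -1.10 ± 0.14); both calls were kept in every leave-one-out fit. Elovl3, a fatty acid elongase, fell by 2.10 ± 0.47 (adjusted p = 0.0373, and 0.129 without 3 months replicate 2). Adjusted over the list alone, 9 members were lower and 2 higher. The list median was -0.51 (fixed-fit camera adjusted p = 3.28e-05, adjusted p = 0.148 with an estimated correlation, fry adjusted p = 0.0015). Tyrp1, a melanosome enzyme, fell from 2.70 to 0.357 FPKM (adjusted p = 0.073 without 3 months replicate 2) and was the 1 called gene of 5 tested melanocyte markers (fixed-fit camera adjusted p = 0.0075, adjusted p = 0.507 with an estimated correlation, fry adjusted p = 0.0854).

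Of 20 genes of the circadian clock, 4 were called lower and 0 higher at 19 months. The period genes Per1, Per2 and Per3 fell by 1.11 ± 0.18, by 1.58 ± 0.21 and by 1.03 ± 0.21 (adjusted p = 0.00429, 0.00139 and 0.022). The calls of Per1 and Per2 were kept in every leave-one-out fit, and that of Per3 was lost in 4 (highest adjusted p = 0.112, without 19 months replicate 3). The list median was -0.43 (fixed-fit camera adjusted p = 3.09e-05, adjusted p = 0.507 with an estimated correlation, fry adjusted p = 0.0449). Adjusted over the list alone, 10 members were lower and 1 higher.

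Of 31 interferon response genes 28 were above 0 at 19 against 3 months. The 3 called higher were Usp18, Irf1 (log2 1.09 ± 0.19) and Ifit1 (log2 1.12 ± 0.24), the last of which was not called without 3 months replicate 1 (adjusted p = 0.15). Camera in the fixed fit gave adjusted p = 2.39e-07 (adjusted p = 0.515 with an estimated correlation, fry adjusted p = 0.14), and adjusted over the list alone 13 were higher and 0 lower. Ribosomal protein genes had a median of 0.23 with 62 of 63 above 0 and 0 called by limma (fixed-fit camera adjusted p = 4.45e-07, adjusted p = 0.73 with an estimated correlation, fry adjusted p = 0.326). The 54 oxidative phosphorylation genes had a median of 0.22 with 0 called (fixed-fit camera adjusted p = 3.28e-05, adjusted p = 0.73 with an estimated correlation, fry adjusted p = 0.285). Glycolysis and hypoxia genes had a median of 0.27 over 23 members, of which Pfkfb3 fell (fixed-fit camera adjusted p = 0.00742, adjusted p = 0.634 with an estimated correlation, fry adjusted p = 0.223, and 0.0563 without 3 months replicate 3). Of 12 immune cell markers, Fcer1g, the Fc receptor gamma chain, fell by 0.90 ± 0.20, a call lost without 3 months replicate 2 (adjusted p = 0.123). For the immune cell, isthmus and TGF-beta lists camera passed in the protein-coding fit (adjusted p = 0.0357, 0.0312 and 0.0498, against 0.639, 0.482 and 0.541 with an estimated correlation) and not in the fixed fit (0.0626, 0.0626 and 0.0721), with medians of -0.25, -0.22 and -0.19. These calls were lost in 2, 2 and 5 leave-one-out fits, at up to 0.28 without 3 months replicate 2, 0.0691 without 19 months replicate 1 and 0.163 without 3 months replicate 2.

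At 24 against 3 months, Usp18 rose from 36.7 ± 6.51 to 96.0 ± 4.99 FPKM (SD, n = 3 each; log2 1.38 ± 0.16, limma adjusted p = 0.0302 in the fixed fit). Npy, the gene of neuropeptide Y, rose from 0.165 ± 0.285 to 4.25 ± 1.36 FPKM (log2 2.17 ± 0.30, adjusted p = 0.0474), and Chit1, a chitinase, rose by a log2 of 0.98 ± 0.14 (adjusted p = 0.0478). The cell adhesion gene Nrcam fell from 8.98 ± 1.79 to 2.18 ± 0.399 FPKM (log2 -1.64 ± 0.16, adjusted p = 0.0193). The zinc transporter gene Slc39a1 fell by 1.54 ± 0.20 (adjusted p = 0.0448), the imprinted gene Peg3 fell by 1.28 ± 0.18 (adjusted p = 0.0478), and Fa2h, a fatty acid hydroxylase, fell by 1.36 ± 0.19 (adjusted p = 0.0483). Lamb3, a chain of the basement membrane laminin 332, fell from 245 ± 26.5 to 105 ± 12.3 FPKM (log2 -1.22 ± 0.16, adjusted p = 0.0448).

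The fixed fit called 29 table rows at 24 against 3 months, 5 higher and 24 lower, with 6 of them listed at 0 at an age. It called 0 once those listed at 0 were left out. At an unadjusted p under 0.05 it held 2655, against 714 by chance. The protein-coding fit called 442 genes, 173 higher and 269 lower, 20 of them among the 29. Of 13 named genes called in the fixed fit and not listed at 0, 0 kept the call in all 9 leave-one-out fits. Nrcam was not called without 24 months replicate 3 (adjusted p = 0.0641), Npy without 24 months replicate 4 (0.14), Usp18 without 3 months replicate 3 (0.105) and Lamb3, Chit1 and Slc39a1 without 3 months replicate 2 (0.14 for each). Peg3 and Fa2h were not called without 24 months replicate 4 (0.145 and 0.141). Without 3 months replicates 1, 2 or 3, 19 months replicate 2, or 24 months replicates 3 or 4, the fixed fit called 10, 10, 11, 12, 7 and 14. Without 3 months replicate 2 or 24 months replicate 4 the protein-coding fit called 150 and 136.

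In the protein-coding fit Lgr5, a receptor that marks follicle stem cells, fell from 121 ± 17.6 to 59.2 ± 7.09 FPKM at 24 months (log2 -1.01 ± 0.17, limma adjusted p = 0.00581). It did not pass the fixed fit (adjusted p = 0.0724). At 19 months it stood at 78.7 ± 19.1 FPKM (adjusted p = 0.0812 against 3 months). Lgr5 was the 1 called gene of 32 in the stem cell identity list (fixed-fit camera adjusted p = 0.253; adjusted over the list alone, 3 higher and 2 lower). Sox9 and Nfatc1 had log2 changes of 0.25 ± 0.15 and 0.35 ± 0.17 that did not pass (adjusted p = 0.344 and 0.234). Crabp1, a retinoic acid binding protein, rose from 18.6 ± 2.68 to 70.4 ± 7.48 FPKM (log2 1.87 ± 0.31), and the amino acid transporter gene Slc38a4 fell from 40.6 ± 15.9 to 8.21 ± 1.81 FPKM (log2 -2.11 ± 0.26). The calls of Lgr5, Crabp1, Slc38a4, Usp18, Npy, Nrcam and Lamb3 were kept in this fit whichever library was left out.

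Of 40 genes of the extracellular matrix, basement membrane and hemidesmosome, 7 were called lower and 0 higher at 24 months. Tnc, the matrix glycoprotein tenascin C, fell from 45.0 ± 18.4 to 8.02 ± 2.58 FPKM (log2 -2.30 ± 0.31, adjusted p = 0.00197). Npnt, nephronectin, a basement membrane ligand of the bulge, fell from 40.5 ± 7.70 to 16.6 ± 3.34 FPKM (log2 -1.23 ± 0.19, adjusted p = 0.00439). The fixed-fit camera adjusted p was 0.0328 (adjusted p = 0.73 with an estimated correlation, fry adjusted p = 0.186), and 0.315 and 0.0539 without 3 months replicate 3 or 24 months replicate 3. Adjusted over the list alone, 11 were lower and 4 higher. Among 34 genes of cell junctions and cytoskeleton, the desmosomal cadherin Dsg3 fell by 0.99 ± 0.18 (adjusted p = 0.0104, and 0.0562 without 3 months replicate 2). Vcl, vinculin, fell by 0.94 ± 0.21 and Acta2, smooth muscle actin, rose by a log2 of 1.42 ± 0.31; both calls were lost without 24 months replicate 4 (adjusted p = 0.108 and 0.0788). That list gave fixed-fit camera adjusted p = 0.333. The endothelial markers Ramp2 and Egfl7, the 2 tested of their list, fell by 0.88 ± 0.15 and by 0.83 ± 0.18, and the call of Egfl7 was lost without 3 months replicate 2 (adjusted p = 0.0993). The adipocyte marker Lpl and the skeletal muscle marker Mylpf, each the 1 tested of its list, were not called at any comparison (smallest adjusted p = 0.786 and 0.204).

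At 24 against 3 months, 7 of 13 tested sebaceous gland genes were called lower and 1 higher. Those called lower included Far2 (log2 -1.93 ± 0.26), Scd1 (log2 -1.14 ± 0.14), Soat1 (log2 -1.41 ± 0.23) and Cidea (log2 -1.80 ± 0.32), calls kept in every leave-one-out fit. The 1 called higher was Mgst1, a glutathione transferase, from 211 ± 26.0 to 366 ± 57.2 FPKM (adjusted p = 0.0123), a gene named after its values were seen. The list median was -0.94 (fixed-fit camera adjusted p = 8.23e-05, adjusted p = 0.148 with an estimated correlation, fry adjusted p = 0.0015). Adjusted over the list alone, 8 were lower and 1 higher. Tyrp1 fell from 2.70 to 0.436 FPKM (adjusted p = 0.0719 without 3 months replicate 2). The 5 melanocyte markers gave fixed-fit camera adjusted p = 0.0139 (adjusted p = 0.508 with an estimated correlation, fry adjusted p = 0.0854, and 0.0719 without 24 months replicate 3).

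Immediate early genes respond quickly to growth factors and stress. At 24 months, of 25 tested members 9 were called higher and 0 lower. Fos stood at 77.6 ± 38.6 FPKM at 3 and 319 ± 143 FPKM at 24 months (log2 2.05 ± 0.39, adjusted p = 0.0104), Egr1 at 51.3 and 162 FPKM (log2 1.62 ± 0.24, adjusted p = 0.00337), and Nr4a1 at 4.77 FPKM at 3 months (log2 1.69 ± 0.33, adjusted p = 0.0121). These 3 calls were kept in every leave-one-out fit. The list median was 0.79 (fixed-fit camera adjusted p = 2.39e-07, adjusted p = 0.515 with an estimated correlation, fry adjusted p = 0.108), and adjusted over the list alone 13 were higher and 1 lower. Epidermal differentiation genes had 4 of 30 members called higher, among them the cornified envelope gene Cnfn (10.1 to 24.1 FPKM, adjusted p = 0.0231, and 0.112 without 3 months replicate 2). That list gave fixed-fit camera adjusted p = 0.0139 (adjusted p = 0.73 with an estimated correlation, fry adjusted p = 0.185), and 0.0573 and 0.135 without 3 months replicate 2 or 24 months replicate 2. The 8 suprabasal keratinocyte markers had a median of 0.43 (fixed-fit camera adjusted p = 0.12), and the calmodulin-like Calm4 was called higher (adjusted p = 0.0167, and 0.0877 without 24 months replicate 4).

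Of 20 BMP signalling genes, Id2, Id4 and Nog had log2 changes of 0.55 ± 0.14, 0.66 ± 0.15 and 0.76 ± 0.20 (adjusted p = 0.0464, 0.0291 and 0.0495; fixed-fit camera adjusted p = 0.124). Without 24 months replicate 4 none of these 3 was called (adjusted p = 0.134, 0.142 and 0.207), and the call of Id2 was lost whichever of the 9 libraries was left out. Of 15 hair germ and matrix genes, 12 were below 0 and the hedgehog receptor Ptch1 fell by 0.86 ± 0.21 (adjusted p = 0.0341, and 0.0997 without 3 months replicate 2). That list gave fixed-fit camera adjusted p = 0.0297 (adjusted p = 0.507 with an estimated correlation, fry adjusted p = 0.0687), and 0.0745, 0.0603 and 0.0987 without 3 months replicates 1 or 3 or 24 months replicate 3. Of 24 WNT genes 2 were called lower and 1 higher (fixed-fit camera adjusted p = 0.214). Among 25 genes of senescence, p53 and cyclin-dependent kinase inhibitors, Igfbp7 and Cdkn1c rose by log2 changes of 1.15 ± 0.21 and 1.04 ± 0.23, and the p53 target Perp fell by 0.69 ± 0.17. In that list 2 were higher and 4 lower when adjusted over the list alone. The calls of all 3 were lost without 3 months replicate 2 (highest adjusted p over the leave-one-out fits = 0.051, 0.0932 and 0.148, the last without 24 months replicate 4; fixed-fit camera adjusted p = 0.693). Of 36 DNA repair genes, Parp1 and Rad50 fell by 0.70 ± 0.15 and by 0.63 ± 0.14 (fixed-fit camera adjusted p = 0.363), with adjusted p = 0.0877 without 24 months replicate 4 and 0.0915 without 3 months replicate 2. Adjusted over the DNA repair list alone, 4 were higher and 5 lower.

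Of 31 interferon response genes 4 were called higher at 24 months, among them Usp18, Dhx58 and Ifi35, the last 2 not called without 24 months replicate 4 (adjusted p = 0.0868 and 0.112). Camera in the fixed fit gave adjusted p = 0.00499 (adjusted p = 0.73 with an estimated correlation, fry adjusted p = 0.26), and 0.0739 without 3 months replicate 3. Ribosomal protein genes had a median log2 change of 0.39 with 62 of 63 above 0. Of these Rpl12 and Rps23 were called higher, and neither was without 24 months replicate 4 (adjusted p = 0.118 and 0.165; fixed-fit camera adjusted p = 8.32e-14, adjusted p = 0.679 with an estimated correlation, fry adjusted p = 0.14). Genes of oxidative phosphorylation went both ways, with 42 of 54 above 0 while Uqcrfs1, Cox5a and Atp5d fell by 0.96 ± 0.15, by 0.88 ± 0.17 and by 0.81 ± 0.16 (fixed-fit camera adjusted p = 0.0626). The calls of Cox5a and Atp5d were lost without 24 months replicate 4 (adjusted p = 0.0604 and 0.0787). Of 38 chromatin regulators 4 were called lower (fixed-fit camera adjusted p = 0.124). They included Hmga1 (log2 -1.16 ± 0.19) and the remodeller Hells (log2 -1.04 ± 0.20, lost without 3 months replicate 2 at adjusted p = 0.062). Of 49 cytokine and JAK-STAT genes 4 were called higher and 1 lower (fixed-fit camera adjusted p = 0.748). Among those called higher, the decoy receptor gene Il1r2 stood at 60.7 FPKM at 3 and 113 FPKM at 24 months (log2 0.90 ± 0.15).

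**Figure D1:**
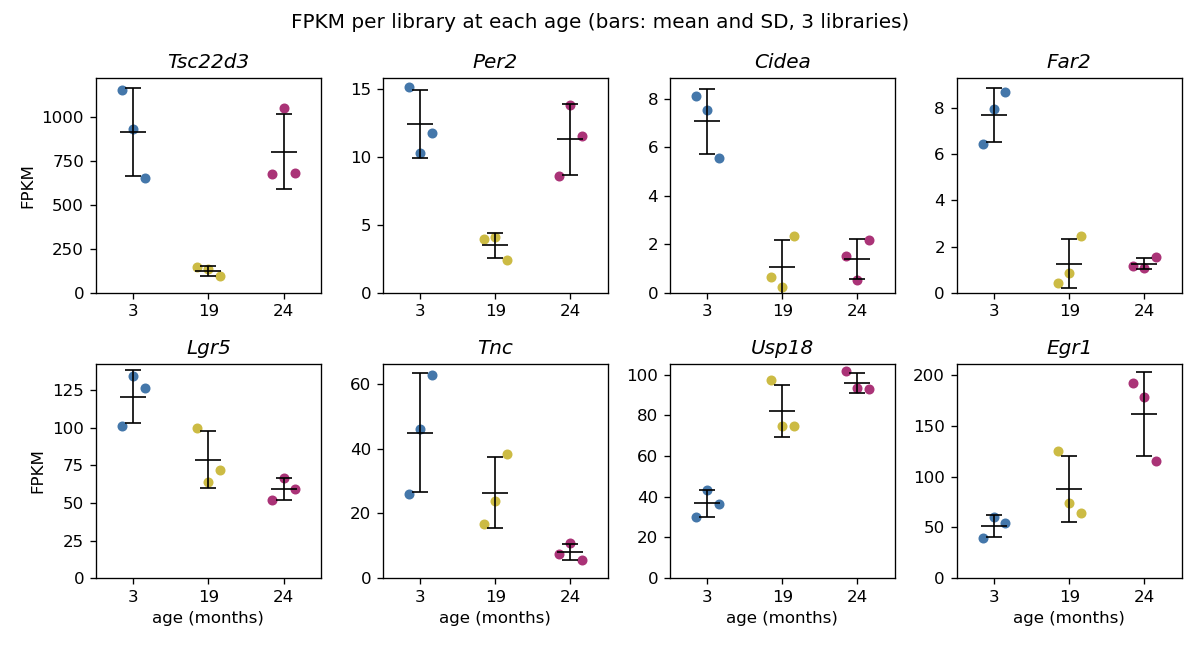
FPKM (linear axes from 0) of 8 protein-coding genes in each of the 9 libraries against age in months; points are libraries, the wide bar is the mean and the whiskers are the SD over 3 libraries, and the lower whisker of Cidea at 19 months ends at the axis. Tsc22d3 lay at 94.1 to 147 FPKM at 19 months and at 653 to 1155 FPKM in the libraries of the other ages, while Far2 was at least 6.42 FPKM at 3 months and at most 2.44 FPKM at the older ages.

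At 24 against 19 months, Tsc22d3 rose from 126 ± 28.0 to 802 ± 214 FPKM (SD, n = 3 each; log2 2.66 ± 0.28, limma adjusted p = 0.0262 in the fixed fit). Fam46b had a log2 change of 1.84 ± 0.22 that missed the threshold in the fixed fit (adjusted p = 0.0567) and was called in the protein-coding fit (adjusted p = 0.00119), there in every leave-one-out fit. In the protein-coding fit Angptl7 rose from 267 ± 98.2 to 1791 ± 610.0 FPKM (log2 2.74 ± 0.32, adjusted p = 0.00149). The transcription factor gene Cebpd rose by a log2 of 1.79 ± 0.27 (adjusted p = 0.00618) and Glul by 1.68 ± 0.21 (adjusted p = 0.0019). These 3 calls, and that of Tsc22d3 in the protein-coding fit, were kept in every leave-one-out fit. Spon2 fell from 22.7 ± 10.6 to 4.97 ± 1.92 FPKM (log2 -1.95 ± 0.35, adjusted p = 0.0187), Tnc fell by 1.56 ± 0.31 and Alox8, a lipoxygenase, fell by 1.11 ± 0.19. These falls were not called without 24 months replicate 4 (adjusted p = 0.103, 0.161 and 0.08).

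The fixed fit called 7 table rows at 24 against 19 months, 3 higher and 4 lower, 5 of them listed at 0 at an age, and 0 with those left out. At an unadjusted p under 0.05 it held 1526, against 714 by chance. Its call of Tsc22d3 was lost in 6 of 9 leave-one-out fits (highest adjusted p = 0.089, without 19 months replicate 2). Without 3 months replicate 1, 19 months replicates 1 or 3, or 24 months replicate 2, the fixed fit called 12, 22, 13 and 13. The protein-coding fit called 107 genes, 82 higher and 25 lower, and 1 gene, Tsc22d3, was called in both fits. Of the 107, 76.6% were higher, against 86.4% of 59 calls after quantile normalisation and 83.3% of 84 after median-of-ratios scaling. Without 19 months replicates 2 or 3, 24 months replicates 2, 3 or 4, or 3 months replicate 2, it called 20, 30, 216, 54, 22 and 46, and with no filter on low values 0.

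Among 20 circadian clock genes, 5 were called higher and 0 lower at 24 against 19 months. Per2 rose from 3.50 to 11.3 FPKM (log2 1.45 ± 0.21, adjusted p = 0.0049). Per1 rose from 6.72 to 15.6 FPKM (log2 1.12 ± 0.18, adjusted p = 0.00795, and 0.0544 without 19 months replicate 2). The fixed-fit camera adjusted p was 8.23e-05 (adjusted p = 0.507 with an estimated correlation, fry adjusted p = 0.0687), and adjusted over the list alone 9 were higher and 1 lower. Of 25 immediate early genes 5 were called higher, including Dusp1 and Jun with log2 changes of 1.23 ± 0.22 and 1.12 ± 0.21 (fixed-fit camera adjusted p = 2.41e-10, adjusted p = 0.507 with an estimated correlation, fry adjusted p = 0.126). Both were among the calls lost in leave-one-out fits (adjusted p = 0.0788 without 19 months replicate 2 and 0.122 without 24 months replicate 4). The metallothionein genes Mt1, Mt2 and Mt4 rose by log2 changes of 0.94 ± 0.17, 1.07 ± 0.17 and 0.95 ± 0.15, within a list of 31 antioxidant genes whose median was -0.12 (fixed-fit camera adjusted p = 0.828). Without 19 months replicate 2 none of the 3 passed (adjusted p = 0.123, 0.0754 and 0.0653). The matricellular gene Ctgf rose from 67.5 to 147 FPKM (log2 1.11 ± 0.14), a call kept in every leave-one-out fit. At 3 months Ctgf stood at 145 FPKM. It was called lower at 19 against 3 months (log2 -1.095, limma adjusted p = 0.00139) and was unchanged at 24 against 3 months (log2 0.01, adjusted p = 0.976).

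Immune cell markers had a median log2 change of 0.62 at 24 against 19 months over 12 genes. The 1 called was Fcer1g (1.52 to 5.92 FPKM, log2 1.45 ± 0.20), kept in every leave-one-out fit. Camera in the fixed fit gave adjusted p = 0.000232 (adjusted p = 0.515 with an estimated correlation, fry adjusted p = 0.14), and adjusted over the list alone 7 were higher. In the isthmus, infundibulum and interfollicular epidermis list, Ly6a (log2 1.19 ± 0.18), Ly6d (adjusted p = 0.184 without 24 months replicate 4) and Mt4 rose among 18 genes (fixed-fit camera adjusted p = 0.00559, adjusted p = 0.507 with an estimated correlation, fry adjusted p = 0.0854, and 0.0662 without 24 months replicate 2). Ribosomal protein genes had a median of 0.17 with 0 called by limma (fixed-fit camera adjusted p = 8.64e-05, adjusted p = 0.775 with an estimated correlation, fry adjusted p = 0.517, and 0.232 without 24 months replicate 4). The epidermal differentiation, oxidative phosphorylation and glycolysis and hypoxia lists also passed camera in the fixed fit (adjusted p = 0.0408, 0.0328 and 0.0332, against 0.73, 0.831 and 0.73 with an estimated correlation; fry adjusted p = 0.423, 0.581 and 0.264). Each lost its call in leave-one-out fits, at up to 0.518 without 24 months replicate 2, 0.838 without 24 months replicate 3 and 0.113 without 24 months replicate 4. Their medians were 0.19, -0.06 and -0.14, and the oxidative phosphorylation list turned direction without 24 months replicate 3. Suprabasal keratinocyte, cell junction and cell cycle genes passed camera in the protein-coding fit (adjusted p = 0.0101, 0.0409 and 0.0448, against 0.584, 0.664 and 0.804 with an estimated correlation) and not in the fixed fit (0.0626, 0.0546 and 0.0748). Those calls were lost in 1, 4 and 2 leave-one-out fits, at up to 0.244 without 24 months replicate 2, 0.12 without 24 months replicate 4 and 0.817 without 19 months replicate 2.

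**Figure D2:**
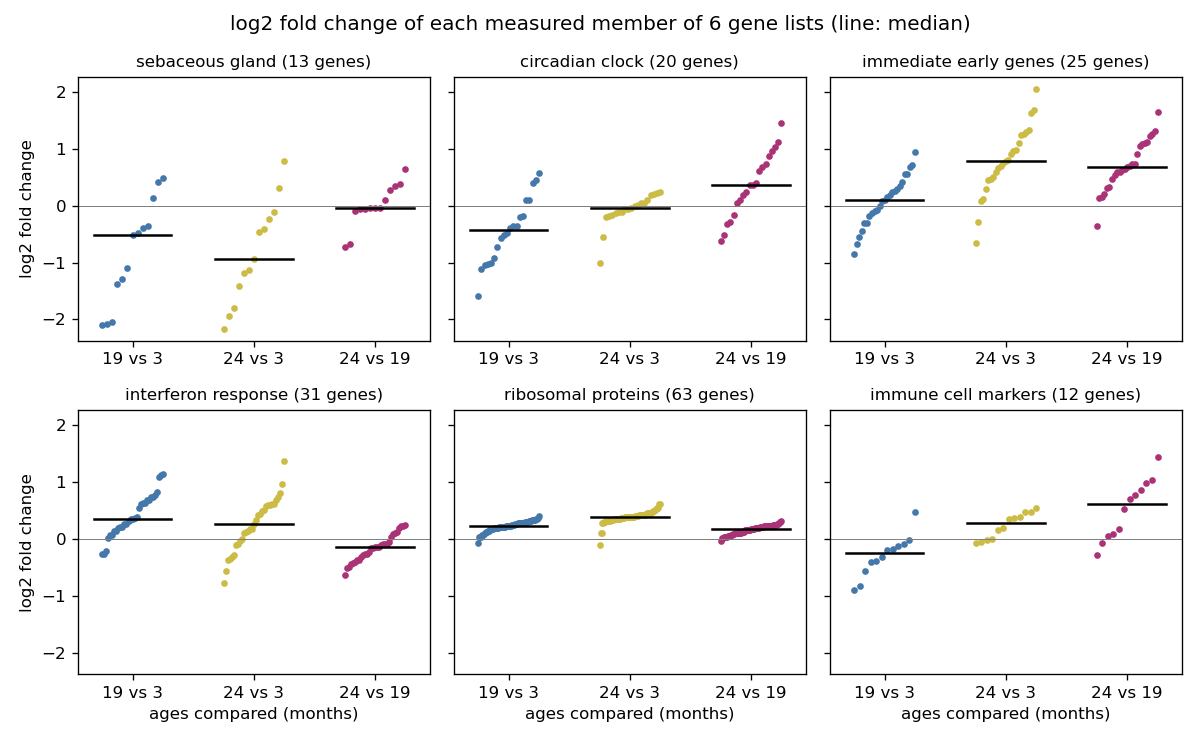
Log2 fold changes, on the log2(FPKM + 1) scale, of each tested member of 6 gene lists at the 3 comparisons of ages, with members in order of size and the line at the median. The circadian clock list has medians of -0.43, -0.05 and 0.37 at 19 against 3, 24 against 3 and 24 against 19 months, and the sebaceous gland list -0.51, -0.94 and -0.04.

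The changes at 19 and at 24 months against the same 3-month libraries overlapped in the protein-coding fit. Both comparisons called 35 genes higher, among them Vit, Usp18 and Mef2c, where independent lists would share 1.04. Both called 44 genes lower, among them Far2, Cidea, Scd1 and Lamb3, where independent lists would share 2.59. Fold changes correlated across genes at 0.616, against 0.501 simulated for unchanged ages with shared controls, and their covariance was 0.067 against 0.0192, a difference of 0.0478. Genes are not independent replicates, and the 3 control libraries could not be split, so part of the overlap may come from the shared controls. Another 21 genes, among them Tsc22d3, Fkbp5, Angptl7, Per1 and Per2, were lower at 19 than at 3 months and higher at 24 than at 19 months, where independent lists would share 0.791. Both of these comparisons use the 19-month libraries with opposite sign, so noise alone gives opposite changes and part of this overlap may come from those libraries. Their fold changes correlated at -0.351, weaker than the -0.502 simulated for unchanged ages. The covariance was -0.0321, larger in size than the -0.0193 simulated. The limma F test for any age called 32 in the fixed fit and 523 genes in the protein-coding fit. Without 3 months replicates 1, 2 or 3, 19 months replicate 2, or 24 months replicates 2, 3 or 4, the fixed fit called 16, 14, 14, 16, 20, 17 and 21. Without 3 months replicates 1 or 2, 19 months replicates 2 or 3, or 24 months replicate 4, the protein-coding fit called 328, 190, 318, 297 and 221.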

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

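Every count below from the protein-coding fit, and both counts for rows listed at 0, were chosen after the result was seen; the other settings were planned before the data were examined. Rows in the order 19 against 3, 24 against 3, 24 against 19 months and any age were called as follows. The fixed fit called 40, 29, 7 and 32. With no filter on low values it called 22, 8, 6 and 17, with a robust prior 72, 224, 27 and 152, with the rows listed at 0 left out 27, 0, 0 and 0, and on protein-coding genes alone 180, 442, 107 and 523. Median-of-ratios scaling gave 52 at 24 against 3 months, and only the libraries of the ages compared gave 20 at 19 against 3 and 15 at 24 against 19 months. The protein-coding fit called 53, 118, 0 and 59 with no filter on low values, 93, 110, 54 and 200 with at least a 2-fold change, and 59 at 24 against 19 months after quantile normalisation. A larger set of genes, a stricter size or fewer libraries accounts for part of these; beyond that the cause was not tested. The replicate block gave 9, 13, 16 and 19 in the fixed fit and 253, 158, 110 and 352 in the protein-coding fit. The 7 pairs of libraries with the same number had deviations that correlated at -0.197 to 0.187, 3 of them over 0.1. The 20 pairs with different numbers correlated at -0.23 to 0.164, 5 of them over 0.1. With so few pairs, this cannot decide whether the numbers pair the samples. With each library left out in turn, the fixed fit ranged over 9 to 37, 7 to 39, 7 to 22 and 14 to 33, and the protein-coding fit over 69 to 230, 136 to 456, 20 to 216 and 190 to 541. In the protein-coding fit the counts that moved by over 1.5 times were, at 19 against 3 months, 69, 92, 85 and 72 without 3 months replicates 1 and 2 and 19 months replicates 2 and 3; at 24 against 3 months, 150 and 136 without 3 months replicate 2 and 24 months replicate 4; and at 24 against 19 months, 46, 20, 30, 216, 54 and 22 without 3 months replicate 2, 19 months replicates 2 and 3, and 24 months replicates 2, 3 and 4. Of named genes called in the fixed fit and not listed at 0, 0 of 15, 0 of 13 and 0 of 1 kept their call in all 9 of these. Named genes called in the protein-coding fit kept theirs in 17 of 45, 24 of 68 and 11 of 35 cases. No named gene that was called changed direction; 207 of 8688 comparisons of a named gene with its main value differed in sign with neither value called. The oxidative phosphorylation list at 24 against 19 months turned direction without 24 months replicate 3. With each library left out its camera adjusted p ranged from 0.000786, without 24 months replicate 2, to 0.838, without 24 months replicate 3, in the fixed fit, and from 0.00104 to 0.789 for the same libraries in the protein-coding fit. Neither scaling moved the median of all genes by over 0.1 on the log2 scale. Since the table keeps no depth, what depth limits could not be given.

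Other splits of the libraries were refitted. For each pairwise comparison 10 splits exist, too few for a share under 0.05. The real fixed fit gave 40, 29 and 7 calls and the highest other splits gave 12, 10 and 9; as many calls as the real split came from 1, 1 and 5 splits. The protein-coding fit gave 180, 442 and 107, and the highest other splits 2, 1 and 1, with 1 split each as high. For the test at any age, 100 splits were taken with the real one included. In the fixed fit the real split was the 1 split with 32 calls or more and the highest other gave 19, but 9 of the 32 were rows listed at 0 by age and 0 calls were left without such rows, so nothing is concluded from it. In the protein-coding fit, chosen with its counts already known, the real split was the 1 split with 523 or more and the highest other gave 96. Since that choice rested on the counts, nothing is concluded from this either.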

Other observations

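The tests of a shared batch, of time of day and of a single library were chosen after the results were seen. Those on glucocorticoid targets and on further sebocyte genes were chosen after the patterns were seen, and their genes were set out before the test was run. Nfkbia and Gadd45g, added late to the glucocorticoid list, were already members of lists tested at 19 against 3 months. Nkg7, Cd7, Ctsw and Lat were picked after their values were seen and outside the rule for named genes, and no list of their cell types was tested. Nkg7, a granule protein of cytotoxic lymphocytes, stood at 5.75 ± 0.76, 2.66 ± 0.75 and 8.77 ± 4.13 FPKM at 3, 19 and 24 months (SD, n = 3 each), a log2 change of 1.36 ± 0.25 from 19 to 24 months (limma adjusted p = 0.0208). Cd7, Ctsw and Lat changed by 1.20 ± 0.27, 0.95 ± 0.20 and 1.05 ± 0.23 (adjusted p = 0.0499, 0.0369 and 0.0457). None of the 4 genes passed at 24 against 3 months.

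In the clock list, 4 of 20 genes were called lower and 0 higher at 19 against 3 months. Camera's call was lost with an estimated correlation (adjusted p = 0.507), while fry passed (adjusted p = 0.0449). A batch shared by the older libraries would not by itself set 19 apart from 24 months. The clock list had a median of -0.047 at 24 against 3 months and -0.43 at 19 against 3. That contrast is how the pattern was picked, so it is no separate test and nothing further is concluded from it. A candidate explanation is lower glucocorticoid exposure at 19 months: of 20 target genes listed for the test (16 planned, 4 added before it was run), 15 were tested, and their median of -0.345 at 19 against 3 months lay below all 10000 expression-matched random lists (-0.349 without Txnip, seen earlier at 24 months, and -0.345 over 11 tested genes of the 16 planned, at percentile 0.03). At 24 against 19 months their median was 0.367, at percentile 100 of the random lists after rounding. But genes move together within libraries, and of the 15 only Foxo3 was called lower at 19 against 3 months and 0 were called by limma at 24 against 19. A separate 11 targets, Per1 and Per2 among them, had already been seen, and all 11 were below 0 at 19 against 3 months. The 15 genes come from the same libraries, so they are no independent test. They cannot tell lower glucocorticoid exposure from another cause of a shared fall. Another time of day of sampling stays open, because Arntl, Npas2 and Clock together changed by 0.159 ± 0.107 while the Per genes changed by -1.24 ± 0.22. These errors are standard errors of the difference between ages in the mean per library (n = 3 each), not limma's. A batch of the 19-month libraries and age itself stay open as untested.

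In the sebaceous gland list, 6 of 13 genes were called lower at 19 against 3 months and 7 at 24 against 3, with 1 called higher at 24. Camera's calls were lost with an estimated correlation (adjusted p = 0.148 for both), while fry passed (adjusted p = 0.0015 for both). Fewer sebaceous cells in the sorted fraction could account for this. The sort was for cells of the bulge, but how many sebaceous cells it let through was not tested. Of 7 further sebocyte genes only Apoc1 and Rdh12 were tested, with a median of 0.478 at 24 and 0.458 at 19 months. That is the opposite direction, but 2 genes are too few to decide. A batch that sets the 3-month libraries apart cannot be told apart from age, since the list had a median of -0.044 at 24 against 19 months, as both would give.

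Of the immediate early genes, 9 of 25 were called higher at 24 than at 3 months and 0 lower. Camera's call was lost with an estimated correlation (adjusted p = 0.515), and fry did not pass (adjusted p = 0.108). A single library is argued against, since the list median at 24 against 3 months stayed at 0.595 or above whichever 24-month library was left out. A batch shared by the older libraries would not by itself set 24 apart from 19 months, where the median was 0.684. The list was picked for being higher at 24 months, so this is no separate test. It also cannot speak to a batch of the 24-month libraries alone. Handling of the skin on the day of sorting, which induces these genes, may differ between ages and stays open beside age, as untested.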
